A study of Etheostoma caeruleum with 63 samples.

How the data were processed

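Liver RNA of adult rainbow darters (Etheostoma caeruleum), a small bottom-dwelling freshwater fish, was measured on 63 single-colour microarrays, 7 for each of 9 river sites. Per the labels' protocols, total RNA was extracted with QIAzol, labelled with the green dye Cy3 and hybridised to an Agilent array. Per the file headers, each array held 15744 spots, of which 15208 were not controls, with 60-base probes. The 15208 spots carried 9041 probe names, 2897 of them on 1 spot, 6121 on 2 spots and 23 on 3 spots. The deposited intensity values were those of Agilent Feature Extraction 10.1.1.1, as the labels name it. The deposited value table of the series held log2 values of 15172 of these spots. Its 63 columns shared 1 distribution, as quantile normalization gives, and each column correlated best with its own array (Spearman rho from 0.997 to 0.997). Which background correction came before that normalization is not given in the sources used here, so the table served only as an alternative.

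No probe could be given a gene name. The description column read "Unknown" for every spot, the gene name column repeated the probe name except for 18 custom probes where it held a number, and no annotation table or genome was used here. The gene lists, cell type markers and named genes fixed before the data were examined therefore could not be applied, and the tests over gene lists were not run. In their place, each comparison with calls names at most 2 probes that rose and 2 that fell: the largest change, and the largest change among probes whose values did not overlap between the fish compared. This rule was chosen after the values were seen. The probe with the largest fall at DSW is also given at DSK3 and DSK4, outside the rule.

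Intensities were analysed as log2 of the background-subtracted processed signal minus the array's 75th percentile. Spots flagged as outliers were left out, which left 0.29% of the values missing, and no spot was saturated. Spots of 1 probe were averaged. A probe counted as detected on an array where at least 50% of its spots were well above background, and was tested if detected on at least 70% of the arrays of at least 1 site, which 7394 probes were. Of these, 108 sets of probes shared a sequence under different names, and their median correlation across fish was 0.944.

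The signal over background limits the precision. The share of spots well above background ran from 62.3% to 90.3% per array (median 80.5%), and the 75th percentile of the processed signal from 84.3 to 605.6 units. The number of fish limits the precision further.

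A pair of arrays carried the same fish number at DSW (replicates 5 and 7) and another at DSK1 (replicates 5 and 7). By a rule fixed before the data were examined, each pair was averaged into 1 fish, because its deviations from the other fish of the site correlated more strongly (0.73 at DSW and 0.70 at DSK1) than those of any other pair of arrays there (at most 0.50 and 0.28). The mean subtracted was that of the arrays outside the pair, which raises the correlation within the pair and lowers that among the others. How far this favoured averaging was not tested. Averaging left 61 fish, with 6 each at DSW and DSK1 and 7 at each other site. Replicate numbers only name the fish and pair none across sites.

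Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided) in 1 fit with a mean for each of the 9 sites. Each of the 6 sites from DSW downstream was compared with the mean of the 3 reference site means, selected pairs of sites were compared directly, and a moderated F-test covered all sites. Benjamini-Hochberg adjusted p-values under 0.05 within a comparison were called. Errors of log2 changes are standard errors (SE) of the fit. They and the p-values rest on 1 spread per probe shared by all sites. The sites did not spread equally: the median SD between fish was 0.314 at US1 and DSK4, 0.421 at DSW and 0.501 at DSK3. An SE or p-value at DSW or DSK3 therefore does not measure the spread of that site's own fish. The procedure was tested on simulated data with the real means and spreads of the 7394 probes, 200 of them changed by known amounts. Probes were drawn independently, each with the same spread at all sites. Fish that deviate over many probes at once were not simulated, so the rates found may not hold for the real fish. With no change simulated, at most 1 probe was called in any of the 16 tests. With changes simulated, in a single draw per comparison, 1.6% to 8.8% of the called probes were unchanged ones. Differences between comparisons in this share, and in the shares recovered given below, may reflect the single draw.

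The arrays lay on 8 slides scanned on 2 days, with 7 or 8 sites on each slide and every site on both days. A site had at most 2 arrays on a slide, so slides entered only as a block, while scan days also allowed a fit within each day. Alternatives fixed beforehand were another background correction (normexp, offset 50, with quantile normalization), quantile normalization, no filter and a stricter filter on dim probes, slide as a fixed or random block, the repeat arrays kept apart, outlier-flagged spots kept, array weights, the deposited value table, no variance trend, a reference without each of its sites, and a fit of only the sites compared. Scan day as a block, each scan day alone, each fish left out, the outlying arrays left out, the log2 75th percentile of the array as a covariate and fits with part of the DSW fish by fish number were added after the data were seen. The mean of the 5 sites below DSW was also compared with the reference sites. That comparison was not planned. For the array of DSK3 replicate 4, a steeper response to signal was tested as an explanation before that of 1 array apart, and both are given. Figures were drawn with matplotlib 3.10.9.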

Results

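The livers came from adult rainbow darters collected in 2013 along the Grand River in Ontario, past the outfalls of the Waterloo and Kitchener wastewater treatment plants. The 3 sites upstream of the urban reach served as reference (US1, US2 and US3, 21 fish). DSW lay below the Waterloo plant (6 fish), INT in the urban reach between the plants (7 fish) and DSK1 below the Kitchener plant (6 fish). DSK2, DSK3 and DSK4 lay further downstream, where recovery was possible (7 fish each). The comparisons ask where along this gradient the liver transcriptome differed from that of upstream fish. All levels are log2 signals relative to the 75th percentile of the array, so a level of 0 is that of a fairly bright probe. The files pair no probe with a gene, and probes are given by their identifiers.

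Over all 9 sites, 969 of 7394 probes (13.1%) differed in the F-test. In separate tests of each comparison, DSW differed from the reference sites at 1223 probes, DSK3 at 200, DSK4 at 41, and INT, DSK1 and DSK2 at 0. Each of these positions was a single site. The tests rest on the spread between fish, and their p-values do not cover how far sites differ with no plant between them. The F-test called 1056 probes with slide as a block and 972 with scan day as a block, but 65 within the first scan day and 0 within the second. Leaving out DSW replicate 2, 5 or 6 brought it down to 469, 485 and 471, and the 75th percentile of the array as a covariate to 609.

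**Figure D1:**
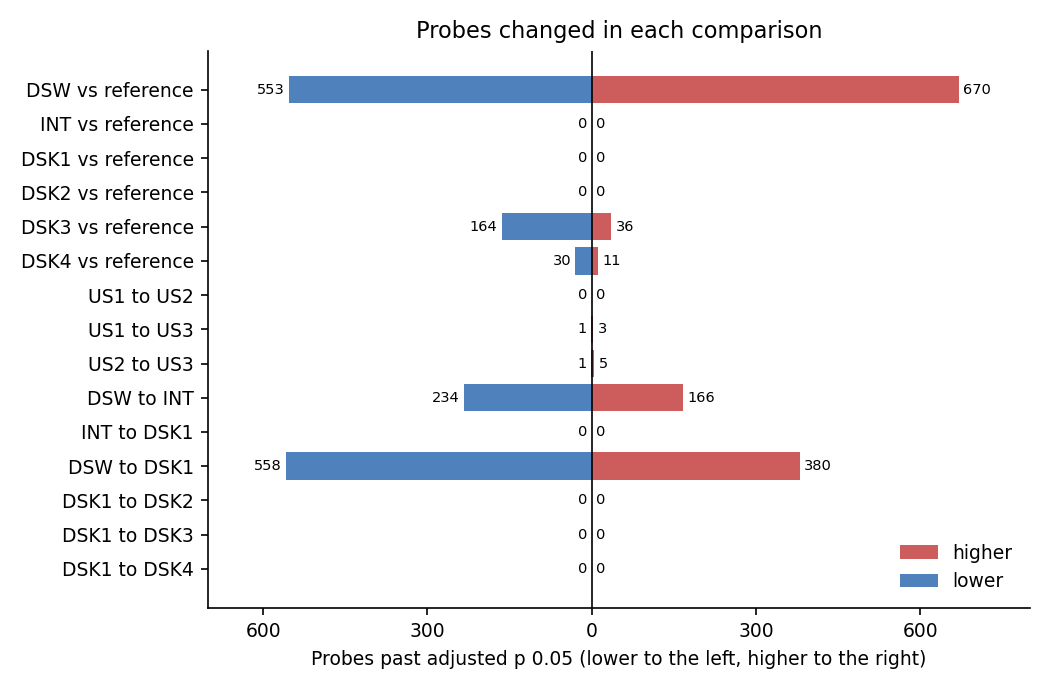
Number of probes past an adjusted p of 0.05 in each of the 15 comparisons, with probes that were lower drawn to the left and higher to the right (a pair of sites is the second minus the first). DSW against the reference sites held 670 higher and 553 lower probes, and INT, DSK1 and DSK2 held none.

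Below the Waterloo plant, at DSW, 670 probes rose and 553 fell against the reference sites, 16.5% of those tested. The median rise was 0.68 and the median fall was -0.63 on the log2 scale, and 126 risen and 79 fallen probes changed by more than 2-fold. The largest rise was that of the custom probe CUST_4_PI428058183 (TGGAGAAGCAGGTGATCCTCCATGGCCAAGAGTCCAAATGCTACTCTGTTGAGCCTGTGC), by 5.98 (SE 1.21, adjusted p 0.000382), from -4.87 ± 1.80 (SD, n = 21) in reference fish to 1.11 ± 5.61 (SD, n = 6) at DSW. It was detected in 16 of the 21 reference fish and in all 6 DSW fish, and 3 of the 6 lay above every reference fish. Its SE and p-value rest on the spread shared by all sites, not on the SD of 5.61 at DSW. With reference values raised to the dimmest detected signal of their array, it was 60-fold higher at DSW (24.9-fold without replicate 6). That fold is an estimate and not a lower limit. Without raised values, the 95% interval of the log2 change ran from 3.56 to 8.41. Probe GT_EA516_un_s_sp_43129 (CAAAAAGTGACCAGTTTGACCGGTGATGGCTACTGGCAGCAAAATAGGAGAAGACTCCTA) was higher (adjusted p 3.28e-10), and all 6 DSW fish lay above the 20 reference fish with a value. It was well above background in 6 of 6 DSW fish and in 5 of 21 reference fish. Elsewhere it was detected in at most 4 of 7 fish (DSK3), so it passed the detection filter only through DSW. This contrast in detection is therefore not separate support. With reference values raised in the same way, the probe was 35.1-fold higher at DSW (23.7-fold without replicate 2). Without raised values, the 95% interval of its log2 change ran from 4.39 to 6.57. Such folds hold only for the scaling used: with normexp its log2 change was 2, and that of GT_EA516_un_s_sp_45744 below was -0.527. Only 7 probes that rose separated all DSW fish from all reference fish and none that fell did, where random order would give 0.025 per direction among the 7394 tested. The largest fall was that of GT_EA516_un_s_sp_45744 (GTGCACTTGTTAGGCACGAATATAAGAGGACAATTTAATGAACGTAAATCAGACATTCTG), which fell by 2.39 (SE 0.381, adjusted p 1.43e-05), from -3.02 ± 0.58 (SD, n = 21) to -5.41 ± 1.33 (SD, n = 6). It was detected in 21 of 21 reference fish and 4 of 6 DSW fish.

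Of the 18 custom probes, whose gene column holds a number in place of a name, 11 were tested. At DSW 4 of these 11 rose, by 0.40 to 5.98, and 1 fell by 0.73. At INT, DSK1, DSK2 and DSK4 none of the 11 was called against the reference sites, and at DSK3 1 fell.

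The fish of DSW differed widely from one another. Each fish was scored by its mean signed log2 difference from the reference fish over the probes called at DSW, with DSW and reference fish left out of the fit that picked the probes for them. DSW replicates 2, 5 and 6 scored 1.19, 1.02 and 1.36. Replicates 3 and 4 scored 0.26 and 0.30 and replicate 1 scored -0.031. The fish of all other sites lay between -0.14 and 0.20. Of the 6 fish, 4 (replicates 2, 3, 5 and 6) carried fish numbers later than those of all other fish in the series. With these 4 alone, 2017 probes were called at DSW, and with the other 2 alone 3 were, where any 2 of the 4 gave from 198 to 2104. With the other 2 alone, GT_EA516_un_s_sp_43129 passed (log2 change 3.52, adjusted p 0.0151), while CUST_4_PI428058183 and GT_EA516_un_s_sp_45744 did not (log2 changes 1.62 and -1.54, adjusted p 0.998 and 0.842). Without replicate 2, 5 or 6 the count at DSW was 629, 769 and 518, and array weights brought it to 476 and ended the call of CUST_4_PI428058183 (2.82, adjusted p 0.125). It was 1327 with slide as a block, 1256 with scan day as a block, 663 and 366 within the first and second scan day, and 875 with the log2 75th percentile of the array as a covariate.

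**Figure D2:**
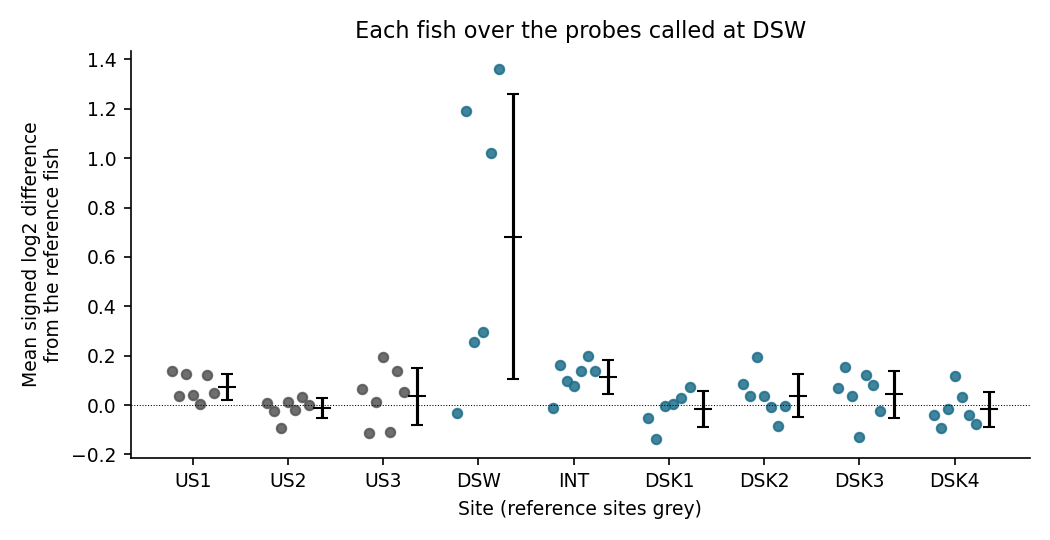
Mean signed log2 difference of each fish (points) from the reference fish over the probes called at DSW, by site, with the mean and SD of the site beside the points. At DSW 3 fish lay between 1.02 and 1.36 and 3 between -0.031 and 0.30, and no fish of another site exceeded 0.20.

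**Figure D3:**
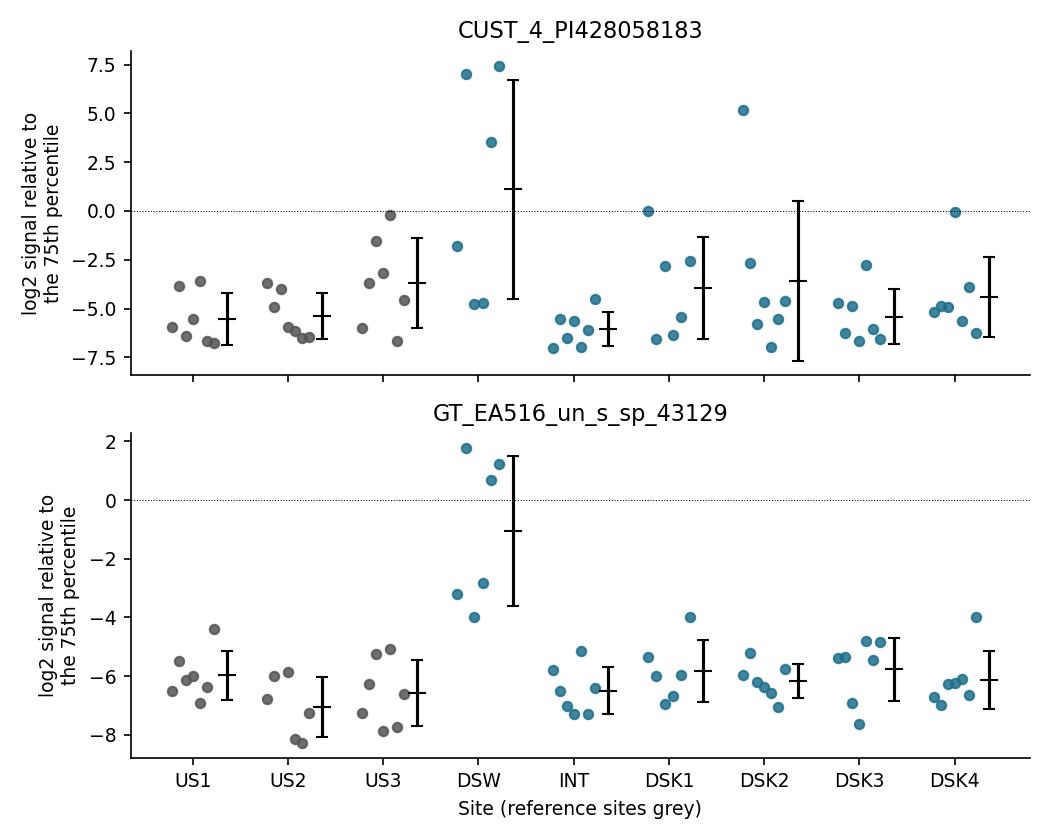
Level of CUST_4_PI428058183 and GT_EA516_un_s_sp_43129 in each fish (points, log2 signal relative to the 75th percentile of the array) by site, with the mean and SD of the site. For the first probe 3 DSW fish and 1 DSK2 fish lay above 3.50, and for the second all 6 DSW fish lay above the 20 reference fish with a value.

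Between the plants, at INT, no probe differed from the reference sites by limma. At an unadjusted p under 0.05, 408 probes did, against 370 expected by chance, and the alternatives called from 0 to 2. CUST_4_PI428058183 was at -6.04 ± 0.89 (SD, n = 7) and detected in 3 of 7 fish, and GT_EA516_un_s_sp_43129 was not well above background in any of the 7. The typical 95% interval of a log2 change at INT was ± 0.36. In simulated data for this comparison 77.6% of probes changed by 1 log2 unit were recovered and 37.3% of those changed by 0.5. Directly from DSW to INT, 166 probes rose and 234 fell. The latter included CUST_4_PI428058183 (adjusted p 0.00171, 95% interval of the log2 change -10.1 to -4.24) and GT_EA516_un_s_sp_43129 (adjusted p 8.11e-08, log2 change -1.99 with normexp). With INT values raised to the dimmest detected signal of their array, the first was 136-fold lower at INT (56.6-fold without DSW replicate 6). In the same way the second was 34.0-fold lower (23-fold without DSW replicate 2). Neither fold is a lower limit. The fold of CUST_4_PI428058183 rested on DSW replicates 2, 5 and 6 (7.00, 3.51 and 7.45), while replicates 3 and 4 (-4.77 and -4.71) lay below INT replicate 7 (-4.52). Its call was lost in 4 of 30 alternatives, among them the first scan day alone (adjusted p 0.11) and the 2 other DSW fish alone (log2 change -2.79, adjusted p 0.999). GT_EA516_un_s_sp_45744 was higher at INT by 2.35 (SE 0.458, adjusted p 0.000985), and all 7 INT fish lay above all 6 DSW fish. Over 31 alternatives its change ran from 0.51 to 3.68, and 3 ended its call. Among them were the second scan day alone (log2 change 1.73, adjusted p 0.135) and the 2 other DSW fish alone (log2 change 1.5, adjusted p 0.806). When the fit held only DSW and INT, 17 probes were called, and GT_EA516_un_s_sp_45744 and CUST_4_PI428058183 did not pass (adjusted p 0.0881 and 0.104). The count was 396 with slide as a block, 432 with scan day as a block, 91 and 25 within the first and second scan day, and 167, 165 and 141 without DSW replicate 2, 5 or 6. It was 1211 with only the 4 later-numbered DSW fish and 8 with only the other 2, 209 with the 75th percentile as a covariate, 889 without DSW replicate 1, 242 without INT replicate 1 and 266 without INT replicate 4. With array weights 178 probes were called and the fall of CUST_4_PI428058183 did not pass (log2 change -3.78, adjusted p 0.116).

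From INT to DSK1 limma called 0 probes (smallest adjusted p 0.48), and 479 passed an unadjusted p of 0.05, against 370 expected by chance. The alternatives called 0 or 1.

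Below the Kitchener plant, at DSK1, no probe differed from the reference sites by limma (smallest adjusted p 0.264). At an unadjusted p under 0.05, 460 probes did (284 higher and 176 lower), against 370 expected by chance, and the alternatives called from 0 to 10. CUST_4_PI428058183 was at -3.95 ± 2.60 (SD, n = 6) and differed from the reference sites by 0.92 (SE 1.21, adjusted p 0.955). GT_EA516_un_s_sp_43129 was detected in 1 of 6 fish and did not pass (adjusted p 0.894). GT_EA516_un_s_sp_45744 was at -4.73 ± 0.75 (SD, n = 6), lower than the reference sites by 1.71, and did not pass (log2 change -1.71, SE 0.381, adjusted p 0.264). In simulated data for this comparison 85.1% of probes changed by 1 log2 unit were recovered and 23.9% of those changed by 0.5.

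In the fit over all sites, DSW and DSK1 differed from each other. From DSW to DSK1, 380 probes rose and 558 fell. CUST_4_PI428058183 fell by 5.07 (SE 1.51, adjusted p 0.0181), but 8 of 29 alternatives ended its call, among them leaving out DSW replicate 2, 5 or 6 (adjusted p 0.11, 0.0598 and 0.125), the 75th percentile as a covariate (adjusted p 0.106), array weights (log2 change -1.69, adjusted p 0.486) and the 2 other DSW fish alone (log2 change -0.701, adjusted p 0.999). GT_EA516_un_s_sp_43129, detected in 1 of 6 DSK1 fish, was lower at DSK1 (adjusted p 6.94e-06, log2 change -2 with normexp). With DSK1 values raised to the dimmest detected signal of their array, it was 22.5-fold lower (15.2-fold without DSW replicate 2). GT_EA516_un_s_xh_43 (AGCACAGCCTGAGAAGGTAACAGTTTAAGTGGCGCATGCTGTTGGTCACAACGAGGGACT) rose by 2.21 (SE 0.321, adjusted p 6.94e-06), from -2.78 ± 0.64 to -0.57 ± 0.73 (SD, n = 6 each), with all 6 DSK1 fish above all 6 DSW fish. GT_EA516_un_s_sp_39737 rose the most, by 3.65 (SE 1.28, adjusted p 0.0489), but of 30 alternatives 17 ended its call and 1 reversed its direction, and its change was -0.15 within the first scan day and 5.62 within the second, and neither passed. With scan day as a block its adjusted p was 0.0529. The 558 lower and 380 higher probes became 814 and 309 with normexp and 620 and 1246 with no filter on dim probes. With the 2 other DSW fish alone, GT_EA516_un_s_xh_43 and GT_EA516_un_s_sp_43129 did not pass (log2 changes 1.65 and -2.8, adjusted p 0.417 each). When the fit held only DSW and DSK1, 0 probes were called (smallest adjusted p for these 4 probes 0.0769). The count was 957 with slide as a block, 940 with scan day as a block, 310 and 251 within the first and second scan day, and 504, 590 and 442 without DSW replicate 2, 5 or 6. It was 1769 with only the 4 later-numbered DSW fish and 1 with only the other 2, 437 with the 75th percentile as a covariate, and 1463 without DSW replicate 1. Across the 7394 probes, which are not independent replicates, the log2 changes at DSW and DSK1 correlated with r = 0.031. Unchanged sites set against the same reference fish gave 0.22 on average in simulation (95% range -0.069 to 0.46). With the reference fish split so that each site had its own, r was -0.056. The covariance was 0.0038, within the range of the simulation (mean 0.014, 95% range -0.0043 to 0.033).

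At the sites where recovery was possible, the test of probes changed at DSK1 and no longer at DSK4 was empty, because none was called at DSK1. From DSK1 to DSK2, DSK3 and DSK4, limma called 0 probes each, and at an unadjusted p under 0.05 it found 258, 1083 and 392, against 370 expected by chance. The alternatives called 0 or 1 in each. The 1083 were 197 higher and 886 lower at DSK3, where the array of replicate 4 stood far from all others. How many of the 1083 rested on that array was not tested. At DSK2 no probe differed from the reference sites (290 at an unadjusted p under 0.05), and all alternatives called 0. CUST_4_PI428058183 reached 5.19 in DSK2 replicate 1 and lay between -6.96 and -2.66 in the other 6 fish of that site.

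At DSK3, 36 probes rose and 164 fell. GT_EA516_an_s_sp_3401 rose by 2.21 (SE 0.642, adjusted p 0.0465), from -0.18 ± 1.54 (SD, n = 21) to 2.04 ± 1.77 (SD, n = 7). GT_EA516_an_as_sp_4704 fell by 1.63 (SE 0.306, adjusted p 0.00303), from -2.23 ± 0.76 to -3.86 ± 0.995. Over 47 alternatives its log2 change ran from -2.03 to -0.602, and 1 ended its call. All 7 DSK3 fish lay below every reference fish for GT_EA516_an_as_sp_2127, which fell by 0.84 (SE 0.209, adjusted p 0.0211). GT_EA516_un_s_sp_45744, the probe with the largest fall at DSW, fell by 1.25 (SE 0.359, adjusted p 0.044); it is named here outside the rule for naming probes. The count rested largely on replicate 4, whose array stood far from all others. Without it, 16 probes were called, 12 of them among the 200. GT_EA516_an_as_sp_2127 then changed less and did not pass (log2 change -0.66, adjusted p 0.204), and GT_EA516_an_as_sp_4704 passed (log2 change -1.26, adjusted p 0.0484). The rise of GT_EA516_an_s_sp_3401 was larger without replicate 4 but did not pass (log2 change 2.53, adjusted p 0.0968). GT_EA516_un_s_sp_45744 did not pass without replicate 4 (log2 change -1.01, adjusted p 0.283), and 21 of 47 alternatives ended its call. The call of GT_EA516_an_s_sp_3401 was lost in 28 of 48 alternatives (adjusted p from 0.0235 to 0.732), among them 16 of the 28 that left out 1 fish, and that of GT_EA516_an_as_sp_2127 in 9 of 47. With normexp the change of GT_EA516_an_as_sp_2127 was -0.269 (adjusted p 0.0821). The split of 36 higher and 164 lower became 23 and 25 with quantile normalization, 34 and 34 with normexp and 21 and 21 in the deposited value table. The count was 392 with slide as a block, 207 with scan day as a block, and 10 and 0 within the first and second scan day. It was 24, 34 and 304 with the reference without US1, US2 or US3, 356 with the 75th percentile as a covariate, 123 without US1 replicate 4, and 380, 324 and 394 without DSK3 replicate 1, 6 or 7.

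**Figure D4:**
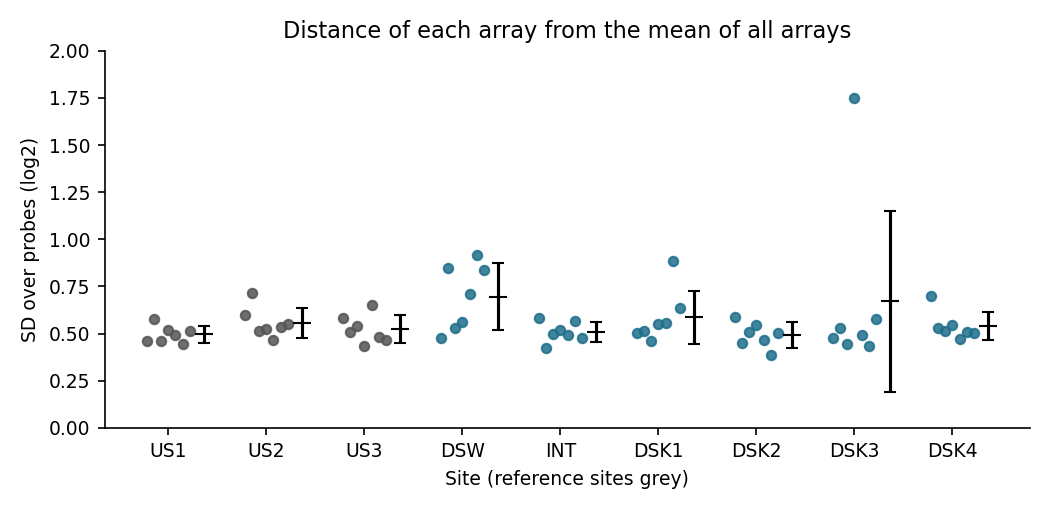
SD over probes of the difference between each array (points) and the mean of all 63 arrays, on the log2 scale, by site, with the mean and SD of the site. DSK3 replicate 4 lay at 1.75, and no other array exceeded 0.92.

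At DSK4, 11 probes rose and 30 fell. GT_EA516_un_s_xh_4523 was detected in 5 of 21 reference fish and 6 of 7 DSK4 fish. Detection at DSK4 alone was enough for the probe to be tested, so this contrast is not separate evidence. Its level was higher at DSK4 (adjusted p 0.0174, log2 change 0.735 with normexp), at -3.22 ± 2.05 (SD, n = 7). With reference values raised to the dimmest detected signal of their array, it was 7.08-fold higher (5.12-fold without DSK4 replicate 4). GT_EA516_an_s_sp_847 (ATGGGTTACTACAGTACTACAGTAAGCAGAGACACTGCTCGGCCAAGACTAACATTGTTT) fell by 2.03 (SE 0.405, adjusted p 0.0138), from -1.46 ± 1.01 (SD, n = 21) to -3.49 ± 0.35 (SD, n = 7). GT_EA516_un_s_sp_45744, called at DSW and DSK3, also changed at DSK4, where it fell by 1.62 (SE 0.359, adjusted p 0.0174), and 7 of 47 alternatives ended that call, 4 of them by leaving out 1 DSK4 fish. At DSK1 its fall was of like size but was not called (log2 change -1.71, SE 0.381, adjusted p 0.264). The split at DSK4 was 16 higher and 24 lower with normexp. The count was 50 with slide as a block, 39 with scan day as a block, 0 within each scan day, 294 with array weights, and 8, 23 and 61 with the reference without US1, US2 or US3. Leaving out DSK4 replicate 1, 2, 4, 6 or 7 gave 22, 12, 15, 16 and 17, and the rise of GT_EA516_un_s_xh_4523 did not pass without replicate 1, 4, 6 or 7 (adjusted p 0.0505, 0.101, 0.0844 and 0.0593).

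Among the reference sites, limma called 0 probes from US1 to US2, 268 passed an unadjusted p of 0.05, and the alternatives called from 0 to 4. US3 differed from US1 at 4 probes and from US2 at 6. At an unadjusted p under 0.05, 782 and 909 did, against 370 expected by chance, beside 798 at DSK4. The SD of the log2 changes over probes was 0.37 from US1 to US3 and 0.43 from US2 to US3, beside 0.36 at DSK3, which had more fish in its comparison. With array weights 72 and 245 probes were called. GT_EA516_an_s_xh_2462 was higher at US3 than at US1 by 1.39 (SE 0.257, adjusted p 0.0102) and than at US2 by 1.46 (SE 0.257, adjusted p 0.00348). GT_EA516_un_s_sp_22917 was higher by 1.35 (SE 0.27, adjusted p 0.0215) and 1.25 (SE 0.27, adjusted p 0.0323), and all 7 US3 fish lay above all fish of the other site in both cases. GT_EA516_an_s_xh_97 was lower at US3 than at US1 (log2 change -0.60, SE 0.131, adjusted p 0.0435). GT_EA516_un_s_sp_28045 was detected in 6 of 7 US2 fish and not well above background in any US3 fish. It was lower at US3 (adjusted p 0.0241, log2 change -0.229 with normexp). With US3 values raised to the dimmest detected signal of their array, it was 3.00-fold lower (2.68-fold without US2 replicate 2). The alternatives ended many of these calls: 5 and 3 of 31 for GT_EA516_an_s_xh_2462 against US1 and US2, 9 and 13 of 31 for GT_EA516_un_s_sp_22917, 17 of 31 for GT_EA516_an_s_xh_97 and 13 of 30 for GT_EA516_un_s_sp_28045. The counts also depended on single fish. Between US1 and US3, leaving out 1 fish gave from 0 (US3 replicate 5) to 16 (US3 replicate 4), and between US2 and US3 from 1 (US2 replicate 1) to 52 (US2 replicate 4). In each of the 2 comparisons, leaving out any of 11 of the 14 fish moved the count by more than 1.5 times. Within either scan day both were 0, and with slide as a block they were 21 and 2.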

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

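The tests of the share of spots well above background, of the fish numbers at DSW, of the array of DSK3 replicate 4 and of the spread and the outlying array at DSK1 were chosen after the results were seen. The rule for the fish numbers was made stricter after its count was seen: the first rule set that count only against pairs of later-numbered fish, and would have made a separate batch a candidate. The fit with slide as a block was planned, but what it would show was written down after its count was seen. The fits with scan day and with the 75th percentile were added after the data were seen and before their own counts were, and the splits of the fish were chosen before their counts were seen.

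The 1223 probes called at DSW against the reference sites were set beside direct tests, which called 400 between DSW and INT and 938 between DSW and DSK1, but 17 and 0 when the fit held only the sites compared. With slide as a block 1327 probes were called, and with scan day as a block 1256 (663 and 366 within the days), which argues against either batch as the whole cause. Of the DSW arrays, 0 lay outside the range of the reference arrays in the share of spots well above background, but all 7 lay above the reference median of the 75th percentile (310.1) and 2 above its maximum (530.7); with that percentile as a covariate 875 probes were called, which argues against brightness as the whole cause and leaves a part open. With the 4 later-numbered DSW fish alone 2017 probes were called and with the other 2 alone 3, but 2 of the 15 pairs of DSW fish gave 3 or fewer, so a separate batch of fish could not be told from differences between single fish and stays open. Later numbers occurred at DSW only, so a difference that may come with the Waterloo outfall, with a later batch or with anything else particular to that site stays open.

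The spread of DSK3 replicate 4 around the mean of all arrays was 1.75, where the other arrays of the site lay between 0.433 and 0.575. Without it the count at DSK3 was 16 in place of 200, so 1 array apart from the others is a candidate explanation for most of that count. Its paired spots correlated at 0.961 (median of the other arrays 0.85), which argues against spot noise as the whole cause. The array held 565 spots flagged as outliers, which were left out, beside a median of 6 over all arrays. Of the variance of its deviation, 1.26% followed the signal level, which argues against a steeper response as the whole cause. Its spike-in slope of 1.27 lay above the 0.954 to 1.09 of the other arrays, so a part stays open. Whether the fish or the handling of its RNA set it apart could not be tested.

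No probe was called at DSK1 by limma, where 460 passed an unadjusted p of 0.05 and the alternatives called from 0 to 10. The median SD between fish was 0.333 at DSK1 and 0.421 at DSW. The fit shared 1 spread per probe over all sites, so a site's own SD had little bearing on its calls. This comparison of SDs therefore cannot decide. The median SE of a log2 change against the reference sites was 0.189 at DSK1 and 0.188 at DSW. DSK1 replicate 6 had a spread of 0.884 around the mean of all arrays (others 0.458 to 0.635), and without it 0 probes were called, which argues against 1 array hiding a change. Changes of 0.5 log2 units, of which 23.9% were recovered in simulated data with 200 changed probes, and larger changes in few probes stay open.

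Of 78 groups of fish or arrays examined for 1 sample far from the others, 8 had one, and chance gives 3.9. Besides the arrays above, these were the level of GT_EA516_an_as_sp_4704 in DSK3 replicate 4 (-6.08, others -3.73 to -3.15), of GT_EA516_an_as_sp_2127 in US1 replicate 7 (-1.68, others -3.03 to -2.54), of GT_EA516_an_s_sp_847 in US3 replicate 1 (-3.64, others -2.17 to -1.12) and of GT_EA516_an_s_xh_2462 in US1 replicate 2 (-0.361, others -1.67 to -1.20). DSK4 replicate 7 had 71.8% of spots well above background (others 78.1% to 82.4%), and DSK4 replicate 1 a spread around the mean of all arrays of 0.701 (others 0.471 to 0.547). No biological explanation was tested for these.

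For each comparison, 100 splits of the same fish into groups of the same sizes were counted, the real one included. The real split alone gave as many probes (1 of 100) for all 9 sites (969, highest other 2), DSW (1223, highest other 58), DSK3 (200, highest other 4), DSK4 (41, highest other 4), US1 and US3 (4, highest other 1), DSW and INT (400, highest other 380) and DSW and DSK1 (938, highest other 825). For US2 and US3, 3 of 100 did (6, highest other 28). For these, the share of splits with as many probes lay under 0.05, uncorrected for the number of comparisons. The splits treat the fish compared as exchangeable. They cannot tell a difference set by the outfalls from differences between sites of any other cause. DSK3 replicate 4 was shuffled with the other fish, and no other split for DSK3 gave more than 4 probes. Which splits placed it in the DSK3 group was not examined, so what that array gives beside other fish stays open. Which fish were grouped in the splits that gave 380, 825 and 28 was not examined. Such a split may differ from the real one by few fish, so what these counts reflect stays open. For INT, DSK1, DSK2, US1 and US2, INT and DSK1, and DSK1 against DSK2, DSK3 and DSK4 the real count was 0, so all 100 splits had to give at least as many (highest others 0, 1, 3, 0, 1, 1, 17 and 6), and the splits decide nothing.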

How the results depend on the processing

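Scan day as a block, each scan day alone, each fish left out, the outlying arrays left out, the 75th percentile as a covariate, the fits with part of the DSW fish and every alternative of the pooled comparison were chosen after the data were seen. The tests over gene lists, cell type markers and named genes, with their alternatives (fry, camera with an estimated correlation, and all probes of a gene averaged), were not run, since the probes carry no gene names. Where a count moved and no reason is given, the cause was not tested.

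The count at DSK2 was 0 under every alternative. At DSW it stayed within 1.5 times of 1223 except with array weights and within a scan day, without replicate 2, 5 or 6, and with the DSW fish split by fish number. At DSK3, DSK4 and between reference sites the counts moved under many alternatives.

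With normexp, 3 probes were called at DSK1 (2 of them not called at DSK4), 68 at DSK3, 29 between US2 and US3 and 1 between DSK1 and DSK3. With quantile normalization these were 3, 2, 48, 16 and 1. In the deposited values, 1 probe was called at DSK1, 42 at DSK3, 15 between US2 and US3 and 1 between DSK1 and DSK3. With no filter on dim probes, 10 were called at DSK1 (9 not at DSK4) and 1866 between DSW and DSK1, and the correlation of the changes at DSW and DSK1 was -0.12. With only probes well above background on every array, which tests fewer probes, DSK3 had 94, DSK4 20 and the pooled comparison of the 5 sites below DSW 14. With outlier-flagged spots kept the pooled comparison had 26.

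With slide as a block, INT had 1, DSK3 392, US1 and US3 21, US2 and US3 2 and the pooled comparison 66. As a random block DSK3 had 333. With the repeat arrays kept apart, which counts 1 fish as 2, DSW and INT had 744 and DSW and DSK1 1510. With array weights, from 0.061 to 1.9 per fish, DSW had 476, INT 1, DSK1 2 (1 not at DSK4), DSK4 294, US1 and US2 4, US1 and US3 72, US2 and US3 245, DSW and INT 178 and the pooled comparison 183.

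With the reference without US1, DSK3 had 24, DSK4 8 and the pooled comparison 0. Without US2 they had 34, 23 and 1. Without US3, INT had 2, DSK3 304 and the pooled comparison 118, and the correlation at DSW and DSK1 was 0.17. With only the sites compared in the fit, and so fewer fish, DSK1 had 1, DSK3 42, DSK4 62, US1 and US3 1, US2 and US3 0, DSW and INT 17, INT and DSK1 1 and DSW and DSK1 0.

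Each scan day alone holds fewer fish. In the first, all sites had 65, DSW 663, DSK3 10, DSW and INT 91 and DSW and DSK1 310, and GT_EA516_un_s_sp_39737 reversed to -0.151 between DSW and DSK1. In the second, all sites had 0, DSW 366, DSK3 0, DSW and INT 25, DSW and DSK1 251 and DSK1 and DSK2 1. In both, DSK4, US1 and US3, US2 and US3 and the pooled comparison had 0. With both outlying arrays (DSK3 replicate 4 and DSK1 replicate 6) left out, DSK3 had 9, DSK4 77, US1 and US3 18, US2 and US3 42, DSW and INT 649 and INT and DSK1 1.

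With the log2 75th percentile of the array as a covariate, all sites had 609, DSW 875, DSK3 356, US2 and US3 2, DSW and INT 209, DSW and DSK1 437 and the pooled comparison 26. With only the 4 later-numbered DSW fish, DSW had 2017, DSW and INT 1211 and DSW and DSK1 1769. With only the other 2 DSW fish these were 3, 8 and 1.

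Leaving out 1 fish gave from 469 to 1338 over all sites, 518 to 1702 at DSW, 0 to 3 at DSK1, 16 to 394 at DSK3, 12 to 60 at DSK4, 0 to 16 between US1 and US3, 1 to 52 between US2 and US3, 141 to 889 between DSW and INT, 442 to 1463 between DSW and DSK1, 0 to 1 between DSK1 and DSK4 and 20 to 53 in the pooled comparison. Of the probes called without DSW replicate 2, 5 or 6, 611 of 629, 753 of 769 and 513 of 518 were among the 1223. The correlation at DSW and DSK1 ran from -0.030 to 0.065.

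CUST_4_PI428058183 lost its call at DSW with array weights (2.82, adjusted p 0.125) and with only the 2 other DSW fish (1.62, adjusted p 0.998), of 47 alternatives. GT_EA516_un_s_sp_43129 kept its call in all 48 (adjusted p at most 0.0151), and GT_EA516_un_s_sp_45744 lost its call with only the 2 other DSW fish (-1.54, adjusted p 0.842). At DSK3 and DSK4, where it was added after its values were seen, 21 and 7 of 47 alternatives ended the call of GT_EA516_un_s_sp_45744. Between DSW and DSK1, 8 of 29 ended that of CUST_4_PI428058183, and between DSW and INT 4 of 30 did. The changes of GT_EA516_un_s_sp_43129 and GT_EA516_un_s_sp_45744 at DSW shrank to 2 and -0.527 with normexp. Signal over background limits dim probes: 1647 of 9041 were not tested.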

Other observations

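The pooled comparison and the choice of the pair of sites given here were made after values were seen, and the splits of the reference fish and of the pooled groups were chosen before their results.

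The mean of the 5 sites below DSW differed from the reference sites at 40 probes, 5 higher and 35 lower, and 873 passed an unadjusted p of 0.05. This comparison was not planned and was first set aside after its count was seen. It rested on the choice of reference site: without US1 it called 0 probes, without US2 1 and without US3 118. Within either scan day it called 0. Of 100 splits of the fish, 1, the real one, gave as many (highest other 2).

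The log2 changes at INT and DSK2 correlated at 0.51 across the 7394 probes, which are not independent replicates. This was the highest of 15 pairs of sites computed, and unchanged sites sharing the reference fish gave 0.24 in simulation (95% range 0.0011 to 0.45). With the reference fish split between the sites the correlation was 0.27, so shared fish may explain part of it. Each part still held fish of all 3 reference sites, so levels particular to those sites stayed shared. DSK2 and DSK3 gave 0.24 in the same split. Whether the shared reference explains all of the correlation could not be decided. Neither site had a probe called by limma (408 and 290 at an unadjusted p under 0.05).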
